A study of Mus musculus with 19 samples.

How the data were processed

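Gene expression was measured on 19 mammary tumours of mice in which the MMTV promoter drives an activated ErbB2 together with Cre recombinase. The tumours belonged to 4 groups: 5 with intact integrin genes (control), 4 labelled Itgb1 knockout, 4 labelled Itgb3 knockout and 6 labelled double knockout. Total RNA was extracted with a column kit from flash frozen end-burden tumours, per the labels' protocols, so each profile mixes tumour cells with stroma and blood vessels. The labels identify tumours and do not say whether each came from a separate animal, so the p-values measure the spread between these samples, part of which may be technical. No batch or scan date was given.

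The deposited table, made by the authors, held 1 normalized log2 intensity per probe set and array for 41345 probe sets of a whole-transcript array. Normalization was done with Affymetrix Expression Console (version not stated), per the submitters' processing notes, and the background correction and summarization are not given in the sources used here. The deposited log2 values were used with no further normalization. They ran from 0.542 to 13.7, with array medians of 4.32 to 4.48 and upper quartiles of 6.35 to 6.42. Each array had a median correlation of 0.969 to 0.980 with the others, and the most similar pair reached 0.984, so no array was a copy of another. The depth of an array is fixed by its design, and the number of arrays limits the precision here. On principal components, the first and second explained 19.7% and 11.7% of the variance.

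A gene symbol was given for 23521 probe sets, several symbols for 1814 and none for 16010. The Entrez identifiers of 23328 probe sets were found in the GRCm38.p6 gene table, and 0 symbols differed. That table was used only for gene names and for the order of genes along chromosomes. Probe sets with 1 symbol were kept where the value reached the median of the table (4.38) on at least 4 arrays, the size of the smallest groups. For the 1082 genes with several probe sets the set with the highest mean over all arrays was kept, which left 14231 genes.

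Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. All 19 arrays entered 1 fit with 1 mean per group and no covariates (15 residual degrees of freedom, 18.7 after moderation), so the groups share 1 estimate of the spread. There were 7 comparisons: each knockout group against control, each pair of knockout groups, and the interaction (double knockout minus control, less both single knockout differences). Tests were two-sided with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene passed at an adjusted p of 0.05. The levels of Itgb1, Itgb3, Erbb2, Insr and Igf1r were also compared with exact two-sided permutation tests, adjusted over these 25 tests.

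Gene lists were tested with limma's cameraPR on the moderated t with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. This test assumes nearly independent genes, so camera with the correlation estimated from the data and fry, a rotation test, were run beside it. Camera asks whether a list moved more than the other genes and fry whether it changed at all, so their counts answer separate questions. The 34 lists were written from general knowledge before the data were examined, and 33 had the 5 measured members needed. They cover integrin subunits, focal adhesion, basement membrane, interstitial matrix, matrix proteases and inhibitors, and markers of fibroblasts, pericytes and smooth muscle, endothelium, adipocytes, skeletal muscle, T and NK cells, B and plasma cells, macrophages, dendritic cells and MHC class II, and neutrophils. They also cover luminal, basal and myoepithelial, milk protein and secretory, epidermal keratinization, mesenchymal transition, ErbB, insulin and IGF, mTORC1, ATF4 and amino acid response, sterol synthesis, fatty acid synthesis, glycolysis and hypoxia, cell cycle, p53 and cell cycle arrest, interferon response, YAP and TAZ target, TGF-beta response and Wnt pathway genes. The red blood cell list had 2 measured members and was not tested. Beside each list stand the members that passed over all genes and with the adjustment over the list alone.

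The genes named in the text were fixed by a rule. Against control these were the 10 genes with the highest and the 10 with the lowest log2 difference among those that passed, made up to 5 per direction by the smallest p where fewer passed. Between knockout groups and for the interaction they were the 5 highest and 5 lowest that passed, or the 3 with the smallest p where none did. Predicted genes, clones, small RNAs, olfactory receptors and antigen receptor segments were counted and not named (Snord123 is named although it was chosen after its values were seen). Also named are the 5 genes of the permutation tests and, for each list that passed, up to 4 members with the smallest p in its direction. The genes named for distal chromosome 11 were chosen after their values were seen, as were the differences with values under the intensity filter raised to it.

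Comparisons that share the control tumours are correlated through them, so the correlation of fold changes was set against 100 simulations of unchanged groups and against 20 splits of the controls. Group labels were reassigned in 100 draws per comparison (35 for the single knockouts, which is every split) and the counts repeated. A running mean over 40 neighbouring genes was scanned along the chromosomes for 14136 placed genes, with a cutoff for each comparison from 1000 shuffles of the gene order.

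The analysis was tested on simulated data made from 14231 genes. Each gene was drawn independently, so the correlation between genes in real tumours is absent. The false calls below, above all of lists, therefore do not carry over to the tumours. With no change 0 genes were called in each of the 7 comparisons, and 1 list was called in the comparison of the double knockout with the Itgb1 knockout. At each size 100 genes were moved up or down at random. Of those moved by a log2 of 1, 82% were recovered for the Itgb1 knockout, 80% for the Itgb3 knockout and 90% for the double knockout against control. At a log2 of 2 the shares were 99%, 95% and 96%. A changed list was called, and 100 of 100 genes of a shifted stretch were found.

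The alternatives chosen beforehand were quantile normalization, centring each array on its median, the mean of the probe sets of a gene, no intensity filter, a filter at the 75th percentile of the table (6.38), a fit on only the groups compared, intensity trend with robust moderation, array weights, the fibroblast and adipocyte list means or the B and plasma cell list mean as covariates, a plain t statistic, leaving out arrays of low correlation, a minimum size of log2 1, and leaving out each tumour in turn. The array median as a covariate and the omission of the genes from Arf2 to the end of chromosome 11 were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The probe sets with no symbol or several symbols were left out of the gene counts and counted apart.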

Results

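Tumours labelled Itgb1 knockout had less Itgb1 transcript, and tumours labelled Itgb3 knockout had less Itgb3 transcript, than tumours with intact integrins. Itgb1 encodes the integrin beta subunit shared by most receptors for collagen, laminin and fibronectin. Its log2 level was 10.16 ± 0.19 (SD) in the 5 controls, 8.70 ± 0.29 in the 4 Itgb1 knockouts, 10.04 ± 0.20 in the 4 Itgb3 knockouts and 8.32 ± 0.48 in the 6 tumours labelled double knockout. Itgb1 fell by 1.46 in the Itgb1 knockouts (SE 0.212, 2.75-fold, limma adjusted p = 0.0217) and fell by 1.84 in the labelled double knockouts (SE 0.191, 3.58-fold, adjusted p = 0.000156). All 4 and all 6 of these tumours lay below every control. The exact two-sided permutation p was 0.00794 for the Itgb1 knockouts, the smallest possible with these group sizes, and 0.00433 for the labelled double knockouts, where the smallest possible is 0.00216 (both 0.0397 after adjustment).

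Itgb3 encodes the beta subunit of the vitronectin receptor and of the platelet fibrinogen receptor. Its log2 level was 8.12 ± 0.25 in control, 8.24 ± 0.51 in the Itgb1 knockouts, 7.01 ± 0.48 in the Itgb3 knockouts and 8.13 ± 0.39 in the tumours labelled double knockout. In the Itgb3 knockouts it fell by 1.12 (SE 0.254, 2.17-fold), with all 4 tumours below every control (exact two-sided permutation p = 0.00794, the smallest possible, and 0.0397 after adjustment). Over all genes the limma adjusted p was 0.723. In the tumours labelled double knockout Itgb3 was not lower than in control (difference 0.01, SE 0.229, adjusted p = 0.986, exact permutation p = 0.955). All 6 lay above the highest Itgb3 knockout tumour (difference 1.13, SE 0.244, adjusted p = 0.0223, exact permutation p = 0.00476, the smallest possible). The same probe set was lower in the Itgb3 knockouts, so it can register a lower level. The labels do not give which exons were deleted, and no genotype was analysed here. The label is kept below, and every direction drawn for this group carries that limit.

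**Figure D1:**
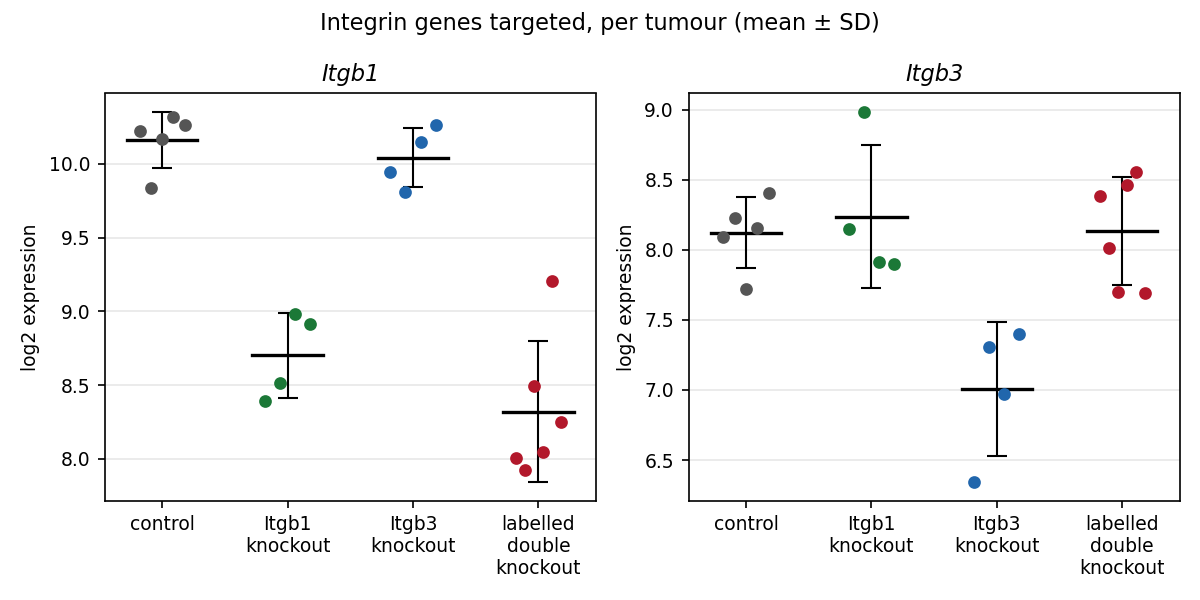
Log2 intensity of Itgb1 and Itgb3 in each of the 19 tumours by group, with a point per tumour, a line at each group mean and bars of ± SD. Itgb1 is low in the Itgb1 knockouts and the tumours labelled double knockout, while Itgb3 is low only in the Itgb3 knockouts (7.01 ± 0.48).

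The mouse gene Erbb2 encodes the receptor tyrosine kinase whose activated form drives these tumours. It did not pass in any knockout group against control (−0.24 in the Itgb1 knockouts, −0.13 in the Itgb3 knockouts and −0.08 in the labelled double knockouts, with exact permutation p = 0.349, 0.524 and 0.677). Whether its probe set detects the transgene is not known, so the level of the driver itself was not tested. The insulin receptor gene Insr differed by −0.03, −0.06 and 0.26 (exact permutation p = 0.841, 0.611 and 0.0238, the last 0.0992 after adjustment). Igf1r, which encodes the receptor of insulin-like growth factors, differed by −0.25, 0.06 and −0.08 (exact permutation p = 0.341, 0.881 and 0.82).

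In the Itgb1 knockouts Itgb1 itself was the only gene that passed against control (0 higher and 1 lower of 14231). At an unadjusted p under 0.05 limma gave 691 genes, where 711.55 are expected by chance. Rab4a, a GTPase of endosome recycling, was the nearest other gene and did not pass (0.91, adjusted p = 0.512). Nor did the tetraspanin gene Cd9 (0.37), Cox20 (0.67), Zfp329 (0.62) or the NF-kappaB subunit gene Rel (0.60), or on the lower side the cyclin-dependent kinase gene Cdk6 (−0.84), Pag1 (−0.56), Lingo3 (−0.93) and the glycogen phosphorylase gene Pygl (−1.34), each with an adjusted p of 0.982. The passing of Itgb1 over all genes was lost (0 genes) without control replicate 1, 3, 4 or 5 or Itgb1 knockout replicate 1, 2 or 4, and with array weights, with the fibroblast and adipocyte covariates and with a plain t statistic.

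Of the 33 lists, 2 were lower in the Itgb1 knockouts than in control. Glycolysis and hypoxia genes had a mean log2 difference of −0.234 (26 genes, 3 above 0, adjusted p = 9.25e-05, adjusted p = 0.929 with an estimated correlation), with Pfkl at −0.43, P4ha2 at −0.50 (−0.32 without control replicate 5) and Egln3 at −0.26 (−0.17 without control replicate 4 or Itgb1 knockout replicate 3). Interferon response genes had a mean of −0.345 (26 genes, 2 above 0, adjusted p = 0.00155, adjusted p = 0.929 with an estimated correlation), with Ifit3 at −0.38, Bst2 at −0.79 and Oas3 at −0.25. Bst2 was −0.20 without control replicate 3, −1.26 without control replicate 1 and −0.44 without Itgb1 knockout replicate 1, and Oas3 was −0.17, −0.44 and −0.13, and −0.45 without Itgb1 knockout replicate 2. Of the members 0 passed, over all genes or with the adjustment over the list alone, and fry gave 0 lists. The mean of the interferon list was −0.11 without control replicate 2, −0.22 without control replicate 3 and −0.05 without Itgb1 knockout replicate 1, and the list no longer passed without any of these. It was −0.61 without control replicate 1 and −0.63 without Itgb1 knockout replicate 2. The glycolysis mean was −0.40 without control replicate 3, −0.14 without control replicate 5, −0.38 without Itgb1 knockout replicate 1 and −0.12 without Itgb1 knockout replicate 3, and the list passed in each case.

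In the Itgb3 knockouts 0 genes passed against control in limma, and 874 had an unadjusted p under 0.05 (711.55 expected, smallest adjusted p = 0.723). The genes with the smallest p that were higher were the homeobox gene Lhx2 (0.65), Acaa1b, which encodes a peroxisomal thiolase (0.73), the potassium channel gene Kcnj14 (0.52), Cep112 (0.51) and the organic anion transporter gene Slc22a6 (0.43, or 0.16 with the 5 controls and 1 Itgb3 knockout under the intensity filter of 4.38 raised to it). Those that were lower were the kinase gene Mast4 (−0.62), Itgb3, the neuroligin gene Nlgn2 (−0.52), the kinase gene Map3k4 (−0.44) and Hif1an (−0.49), which encodes an inhibitor of hypoxia-inducible factor. All had an adjusted p of 0.723.

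Milk protein and secretory genes were higher in the Itgb3 knockouts as a list (21 genes, 16 above 0, mean 0.575, adjusted p = 0.000597, adjusted p = 0.664 with an estimated correlation). The casein genes Csn1s2a (2.53, SE 0.699) and Csn1s1 (2.03, SE 0.632) and Folr1 (0.47) led it, and 2 members passed with the adjustment over the list alone and 0 over all genes. Lower lists were focal adhesion (29 genes, 4 above 0, mean −0.194, adjusted p = 0.000597, adjusted p = 0.213 with an estimated correlation), with Actn1 at −0.41, Rsu1 at −0.28 and Pxn at −0.26 (−0.17 without control replicate 2), and basement membrane (21 genes, 3 above 0, mean −0.189, adjusted p = 0.0103, adjusted p = 0.664 with an estimated correlation), with Lamb1 at −0.59, Nid2 at −0.39 and Nid1 at −0.50. Interstitial matrix genes were also lower (29 genes, 7 above 0, mean −0.321, adjusted p = 0.0103, adjusted p = 0.843 with an estimated correlation), with Fn1 at −1.13, Fbln2 at −0.53 and Col1a1 at −0.68. Of the members of these 3 lists 0 passed by either adjustment, and fry gave 0 lists. Fibroblast markers had a mean of −0.272 (5 of 19 above 0, adjusted p = 0.226) and pericytes and smooth muscle one of −0.154 (2 of 14 above 0, adjusted p = 0.226), and in Itgb3 knockout replicate 2 the fibroblast mean was −1.02 beside an interstitial matrix mean of −1.19. Without that tumour Fn1 was −0.41 and Col1a1 −0.17, and Col1a1 was −1.03 without Itgb3 knockout replicate 3. The interstitial matrix mean was −0.03 without Itgb3 knockout replicate 2 and −0.21 without control replicate 4, where the list did not pass, and −0.53 without Itgb3 knockout replicate 3. Basement membrane did not pass without control replicate 4 (−0.14) or Itgb3 knockout replicate 2 (−0.15).

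**Figure D2:**
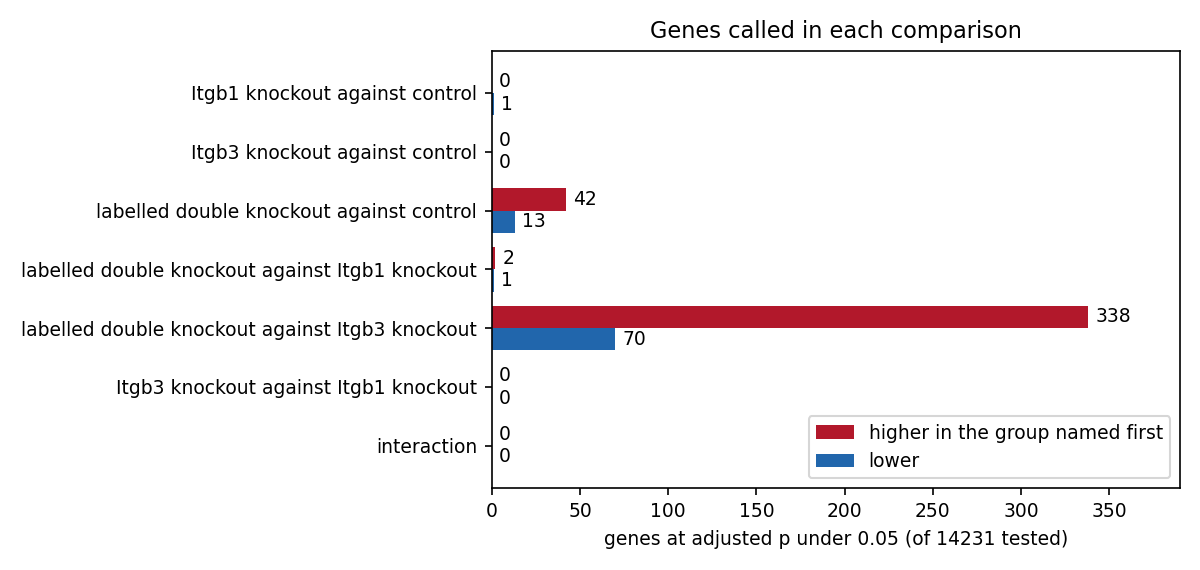
Number of genes higher and lower in each of the 7 comparisons at an adjusted p of 0.05. The counts are large only where the tumours labelled double knockout are compared with control (42 higher, 13 lower) and with the Itgb3 knockouts (338 higher, 70 lower).

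Gabra4, which encodes a subunit of the GABA-A receptor, changed most in the tumours labelled double knockout. It fell by 5.06 against control (SE 0.557, adjusted p = 0.000194) and ranged from 2.56 to 4.94 in the 6 tumours and from 7.47 to 9.83 in the 5 controls. Of the 6 tumours 5 lay under the intensity filter (4.38), so the size is not exact, and with such values raised to the filter the difference was −3.79. Samd5, which encodes a protein with a sterile alpha motif, rose by 2.29 (SE 0.341, adjusted p = 0.00607, 2.19 with the 2 controls under the filter raised to it), and Cd14, the lipopolysaccharide co-receptor of macrophages, rose by 1.59 (SE 0.229, 3.01-fold, adjusted p = 0.00514). For all 3 genes each of the 6 tumours lay beyond every control and every single knockout tumour. In all 42 genes rose and 13 fell, and 2398 had an unadjusted p under 0.05. Itgb3 was not lower in these tumours, so the differences describe tumours with the label and low Itgb1.

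Other genes that rose included transporters and enzymes. Among them were the proton pump subunit gene Atp6v1c2 (2.18, SE 0.402, adjusted p = 0.0235), the monocarboxylate transporter gene Slc16a6 (1.80, SE 0.343, adjusted p = 0.0308), the organic ion transporter gene Slc22a23 (1.63, SE 0.275, adjusted p = 0.0133), Ace, which encodes angiotensin-converting enzyme (1.26, SE 0.242, adjusted p = 0.0308), and the galactosyltransferase gene B3galt5 (1.25, SE 0.225, adjusted p = 0.0201). The protein kinase C alpha gene Prkca (1.23, SE 0.221, adjusted p = 0.0201), the F-box gene Fbxl7 (1.16, SE 0.208, adjusted p = 0.0201) and Foxd2os, transcribed opposite a forkhead gene (1.15, SE 0.154, adjusted p = 0.00251), completed the leading 10. All 6 tumours exceeded every control for these genes, except that 5 did for Prkca.

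Besides Gabra4 and Itgb1, genes that fell were Rtp4 (−1.99, SE 0.409, adjusted p = 0.0499) and Xaf1 (−1.91, SE 0.412, adjusted p = 0.0499), which interferon induces, with all 6 tumours below every control. Galnt12, which starts mucin glycosylation (−1.79, SE 0.374), the homeobox gene Meis1 (−1.34, SE 0.287), Tdrkh of the piRNA pathway (−1.23, SE 0.265) and the cytochrome P450 gene Cyp4b1 (−0.91, SE 0.194) each had an adjusted p of 0.0499 and 5 of 6 tumours below every control. The actin bundling gene Pls1 (−0.99, SE 0.19, adjusted p = 0.0308) and Ppp4r4, a phosphatase subunit gene (−0.73, SE 0.121, adjusted p = 0.0121), fell with all 6 below. Raised to the intensity filter in the same way, Ppp4r4, with all 6 under it, differed by −0.28 and Foxd2os, with 4 of 5 controls under it, by 0.85. In 42 genes all 6 tumours lay above the other 13 and in 8 all lay below, where 0.525 of each are expected by chance among 27132 splits.

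Gabra4 and Itgb1 passed in every setting tried and without any single tumour, and Samd5, Cd14 and Foxd2os lost it only in the fit on the groups compared, while the calls at an adjusted p of 0.0499 were lost in over 20 settings. The count of 55 (42 higher and 13 lower) became 100 (87 higher and 13 lower) with arrays centred on their medians. It was 14 without control replicate 1, 16 without control 2, 35 without control 4, 105 without control 5, 33, 26 and 24 without Itgb1 knockout replicate 2, 3 and 4, 24, 26, 24 and 26 without Itgb3 knockout replicate 1 to 4, and 18, 14, 31 and 125 without labelled double knockout replicate 1, 2, 3 and 5.

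**Figure D3:**
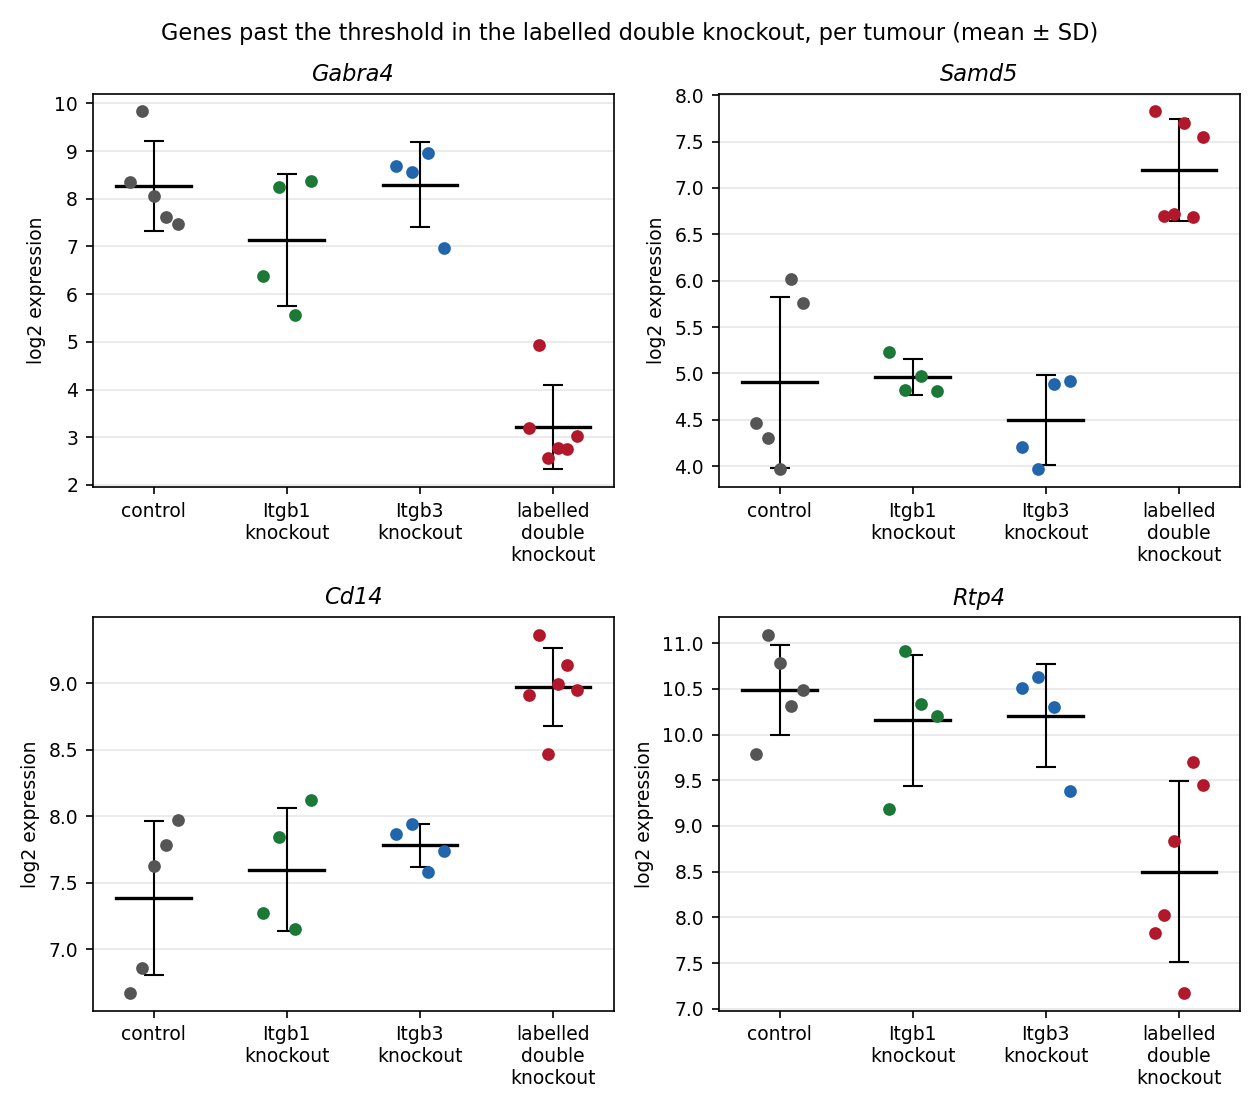
Log2 intensity of Gabra4, Samd5, Cd14 and Rtp4 in the 19 tumours by group, with a point per tumour, a line at each group mean and bars of ± SD. The tumours labelled double knockout lie apart for Gabra4 (−5.06 against control), Samd5 (2.29) and Cd14 (1.59), and overlap the single knockouts for Rtp4 (−1.99).

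Interferon response genes were lower in the tumours labelled double knockout as a list (26 genes, 3 above 0, mean −1.16, adjusted p = 3.15e-15, adjusted p = 0.372 with an estimated correlation). Of the 26, 0 passed over all genes, and 21 were lower with the adjustment over the list alone. Rsad2 (−1.64, adjusted p = 0.0577), Mx2 (−1.94, adjusted p = 0.0577) and Irf9 (−1.09, adjusted p = 0.058), an antiviral enzyme, an antiviral GTPase and a transcription factor of the pathway, were its leading members. The mean of the list relative to control ran from −1.79 to −0.356 in the 6 tumours and from −1.07 to 0.952 in the 5 controls, so the groups overlapped.

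Matrix and adhesion lists were higher in these tumours. Interstitial matrix had a mean of 0.475 (29 genes, 27 above 0, adjusted p = 0.000333, adjusted p = 0.495 with an estimated correlation), led by Col15a1 (0.70), Col6a3 (0.51) and Tnc (1.17), with 0 members past by either adjustment. Its mean relative to control was −0.397 in labelled double knockout replicate 5, where fibroblasts were at −0.6, and 0.347 to 0.937 in the other 5, against −0.254 to 0.447 in the controls, so the groups overlapped. Basement membrane (21 genes, 19 above 0, mean 0.246, adjusted p = 0.0141, adjusted p = 0.372 with an estimated correlation) had 1 member, Hspg2 (0.60), past over the list alone. Integrin subunits (24 genes, 19 above 0, mean 0.201, adjusted p = 0.0372, adjusted p = 0.372 with an estimated correlation) had 2 higher and 1 lower over all genes and 4 higher and 1 lower over the list alone: the collagen receptor gene Itga2 (0.93, SE 0.175, adjusted p = 0.0279) and the laminin receptor gene Itgb4 (0.91, SE 0.198, adjusted p = 0.0499) rose. Focal adhesion (29 genes, 21 above 0, mean 0.159, adjusted p = 0.0481, adjusted p = 0.372 with an estimated correlation) was led by Parva (0.41), Vasp (0.33) and Dock1 (0.36), with 0 past by either adjustment. Matrix proteases and inhibitors (23 genes, 19 above 0, mean 0.343, adjusted p = 0.00459, adjusted p = 0.475 with an estimated correlation) had 3 members past over the list alone, with Adamts4 at 0.78, Plaur at 0.60 and Timp1 at 1.14.

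Lists of cell types that were higher were pericytes and smooth muscle (14 genes, 13 above 0, mean 0.347, adjusted p = 0.0141, adjusted p = 0.378 with an estimated correlation, 3 past over the list alone), with Cspg4 at 0.48, Kcnj8 at 0.97 and Mylk at 0.49, and endothelium (20 genes, 18 above 0, mean 0.221, adjusted p = 0.0141, adjusted p = 0.604 with an estimated correlation), with Tie1 at 0.44, Tek at 0.70 and Eng at 0.48 and 0 past by either adjustment. Macrophage markers (22 genes, 21 above 0, mean 0.353, adjusted p = 0.00266, adjusted p = 0.495 with an estimated correlation) included Cd14, the 1 member past over all genes of the 2 past over the list alone, with Adgre1 at 0.63 and Csf1r at 0.53. Basal and myoepithelial markers (15 genes, 14 above 0, mean 0.237, adjusted p = 0.0362, adjusted p = 0.475 with an estimated correlation) had 1 member past by either adjustment, the Notch ligand gene Jag1, which rose (0.96, SE 0.199, adjusted p = 0.0499).

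The lists of mesenchymal transition, TGF-beta response, YAP and TAZ targets, the insulin and IGF pathway and p53 were higher as well. Mesenchymal transition genes (20 genes, 17 above 0, mean 0.371, adjusted p = 0.00126, adjusted p = 0.372 with an estimated correlation) had 5 past over the list alone, and the Wnt ligand gene Wnt5a rose (1.10, SE 0.177, adjusted p = 0.0094) while Mmp14 (0.88), Tgfb2 (0.90) and Cdh11 (1.14) did not pass over all genes. TGF-beta response genes (23 genes, 20 above 0, mean 0.329, adjusted p = 0.000201, adjusted p = 0.342 with an estimated correlation) were led by Smurf2 (0.50), Tgfbr2 (0.56) and Ltbp4 (0.48), with 1 past over the list alone. YAP and TAZ target genes (25 genes, 19 above 0, mean 0.296, adjusted p = 0.0141, adjusted p = 0.372 with an estimated correlation) had 4 past over the list alone, with Ptpn14 at 1.01, Fjx1 at 0.55 and Myof at 0.51. Insulin and IGF pathway genes (25 genes, 19 above 0, mean 0.206, adjusted p = 0.0473, adjusted p = 0.372 with an estimated correlation) had 2, with Igfbp4 at 0.86, Igf2 at 0.38 (0.24 with 3 controls raised to the filter) and Pik3r3 at 0.98. Genes of p53 and cell cycle arrest (21 genes, 17 above 0, mean 0.19, adjusted p = 0.0149, adjusted p = 0.372 with an estimated correlation) had 3, with Phlda3 at 0.70, Cdkn2b at 0.52 and Btg2 at 0.57.

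The other 18 lists did not pass against control in these tumours. Their means were 0.253 for fibroblast markers (adjusted p = 0.145), 0.0978 for adipocytes (0.901), 0.149 for T and NK cells (0.556), 0.142 for B and plasma cells (0.834), 0.104 for dendritic cells and MHC class II (0.96) and 0.329 for neutrophils (0.0741). Among epithelial lists they were 0.193 for luminal markers (adjusted p = 0.556), 0.124 for milk protein and secretory genes (0.901) and 0.415 for keratinization (0.19). For pathways they were −0.0633 for ErbB receptors and ligands (adjusted p = 0.901), 0.0346 for mTORC1 (0.746, its member Rptor rose by 0.58), 0.206 for sterol synthesis (0.138), 0.054 for fatty acid synthesis (0.901), −0.0383 for glycolysis and hypoxia (0.344) and 0.125 for Wnt (0.596). Skeletal muscle (0.0306, adjusted p = 0.556), ATF4 and amino acid response (0.00838, 0.954) and the cell cycle (0.00603, 0.556) had means above 0 although the test pointed lower. Of the 33 lists 15 passed, 0 passed with an estimated correlation and 9 passed in fry.

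Leaving out 1 tumour ended the passing of 10 of these 15 lists. Those of integrin subunits (lowest mean 0.141) and focal adhesion (0.104) did not pass without control 1, 2 or 3, Itgb1 knockout 1, or labelled double knockout 1 or 3. The same held for integrin subunits without labelled double knockout 2 or 5, and for focal adhesion without Itgb1 knockout 2, 3 or 4 or labelled double knockout 6. Insulin and IGF genes (0.173) were lost without control 1, 2 or 3, Itgb1 knockout 1 or 3, or labelled double knockout 1, 3, 4 or 6, and basal markers (0.173) without control 1, 2 or 3 or labelled double knockout 1, 2 or 3. Endothelium (0.162) was lost without control 1 or 5 or labelled double knockout 2, 3 or 6, and basement membrane (0.200) without control 1 or 3 or labelled double knockout 4. Pericytes (0.286) and YAP and TAZ targets (0.240) were lost without control 2 or 3, p53 genes (0.135) without control 1 or 5, and proteases (0.276) without control 3. Interferon response, interstitial matrix, macrophage, mesenchymal and TGF-beta lists passed without any single tumour.

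**Figure D4:**
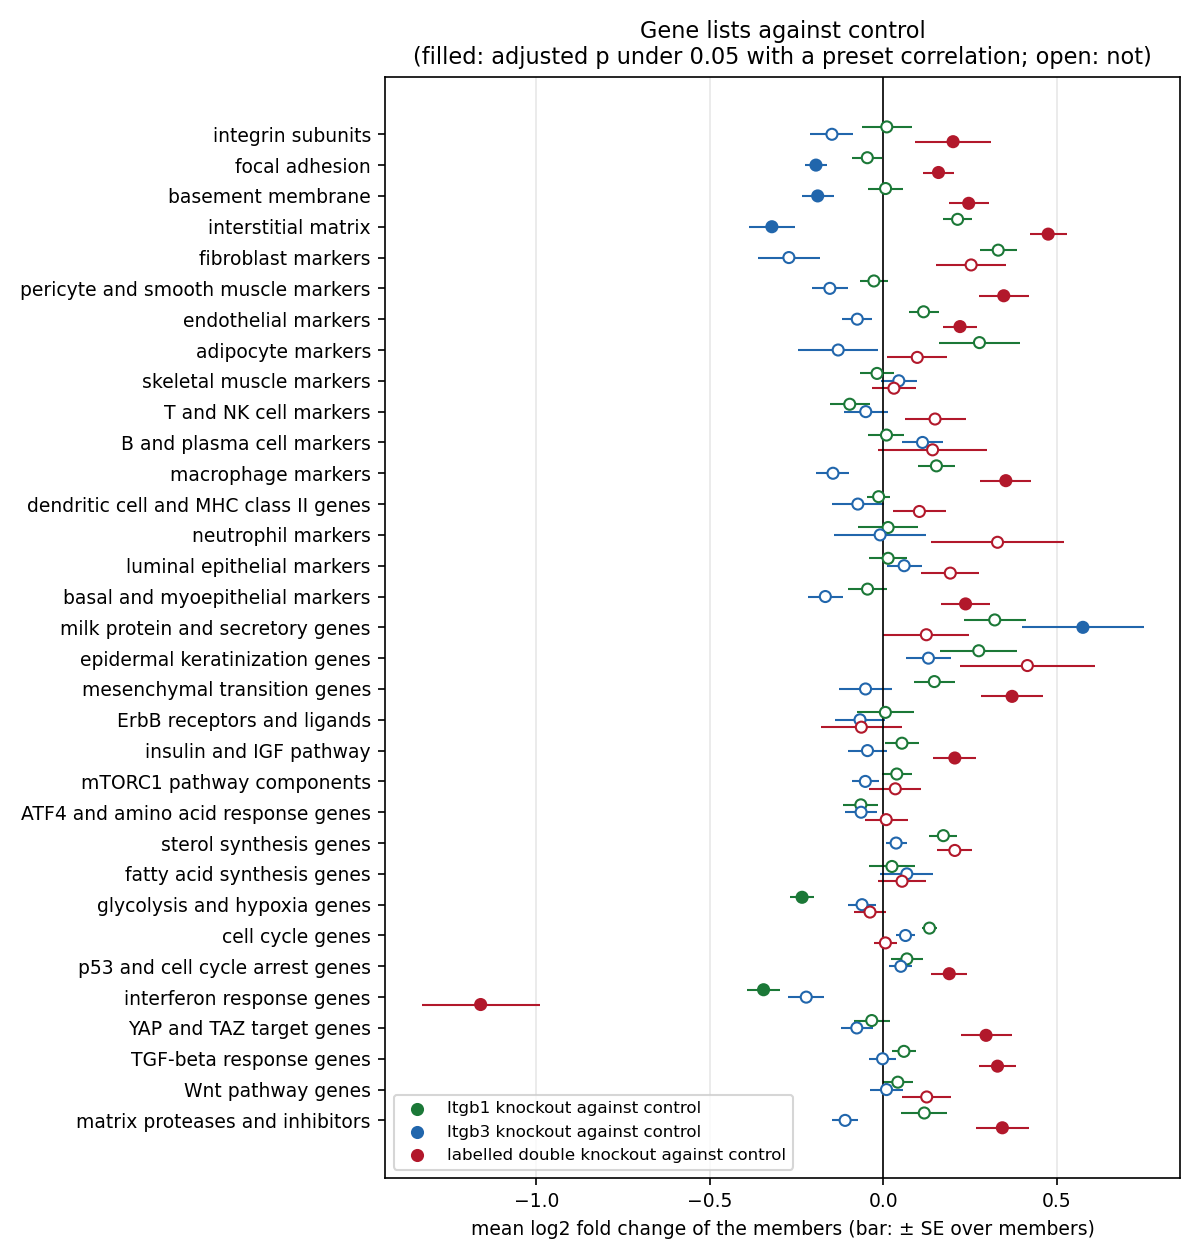
Mean log2 difference from control of the members of each gene list in the 3 knockout groups, with bars of ± SE over members and filled points where the list passed with a preset correlation. Interferon response genes are lowest in the tumours labelled double knockout against control (−1.16), and 0 lists passed with an estimated correlation.

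Against the Itgb1 knockouts, Gabra4 fell by 3.93 (SE 0.593, adjusted p = 0.0185, −2.67 with values raised to the intensity filter) and Samd5 rose by 2.24 (SE 0.363, adjusted p = 0.0327) in the tumours labelled double knockout. The small RNA gene Snord123, chosen after its values were seen, also passed (2 higher and 1 lower in all), and 1744 genes had an unadjusted p under 0.05. Cd14 was 1.37 higher and did not pass (adjusted p = 0.0767). Neither Itgb3 (−0.10, exact permutation p = 0.743) nor Itgb1 (−0.38, exact permutation p = 0.2) passed here. The count of 3 was 8, 6, 15, 0, 1, 0, 0, 0, 24 and 8 without control replicates 2 and 5, Itgb1 knockout replicates 1, 2, 3 and 4 and labelled double knockout replicates 1, 4, 5 and 6, and 0 with the covariates of either kind.

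Of the 33 lists 15 passed in this comparison, 13 higher and 2 lower, 0 with an estimated correlation and 3 in fry. Interferon response genes had a mean of −0.815 (adjusted p = 1.05e-06, adjusted p = 0.544 with an estimated correlation), with Mx2 at −1.64, and the cell cycle one of −0.126 (0.0339, 0.805), with Cdca8 at −0.45. In the same order, the higher ones were YAP and TAZ targets 0.329 (0.000384, 0.162, Fjx1 0.59), TGF-beta response 0.27 (0.000384, 0.162, Smurf2 0.42), focal adhesion 0.205 (0.00226, 0.162, Git1 0.57), pericytes 0.374 (0.00308, 0.343, Kcnj8 1.20), basement membrane 0.239 (0.00646, 0.343, Col4a6 1.26) and basal markers 0.283 (0.00646, 0.428, Jag1 1.03). The remaining ones were integrin subunits 0.191 (0.0213, 0.343, Itgb4 0.82), interstitial matrix 0.261 (0.026, 0.704, Col11a1 0.76), mesenchymal genes 0.225 (0.026, 0.55, Wnt5a 0.88), proteases 0.226 (0.026, 0.604, Adamts4 0.60), macrophages 0.2 (0.0398, 0.704), glycolysis 0.196 (0.0398, 0.704, Pfkl 0.62) and the insulin and IGF pathway 0.153 (0.0462, 0.343, Igfbp4 0.84). Of all these members 0 passed over all genes. With the adjustment over the list alone, 4 basement membrane genes, 3 TGF-beta genes, 2 pericyte and 2 basal markers were higher. So was 1 gene each of integrin subunits, focal adhesion, macrophages, mesenchymal genes, the insulin and IGF pathway, glycolysis and YAP and TAZ targets, and 1 TGF-beta gene was lower.

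Without Itgb1 knockout 4 the lists of basement membrane (lowest mean 0.210), pericytes (0.310) and basal markers (0.230) did not pass, nor did integrin subunits (0.155) without Itgb1 knockout 3 or 4. Interstitial matrix (0.169) and macrophages (0.116) were lost without Itgb1 knockout 3 or 4 or labelled double knockout 1, 2 or 3. Mesenchymal genes (0.175) and proteases (0.146) were lost without Itgb1 knockout 3 or 4 or labelled double knockout 2 or 3. The insulin and IGF list (0.123) was lost without control 2, Itgb1 knockout 3 or 4, or labelled double knockout 1, 3 or 6. Glycolysis (0.0848) was lost without Itgb1 knockout 3 or 4 or labelled double knockout 2, 3, 4 or 6, and the cell cycle (mean −0.00331 without labelled double knockout 5) without Itgb1 knockout 3 or 4 or labelled double knockout 1, 3 or 5. Some lists passed with a moved mean. Interferon response genes had −0.525 without Itgb1 knockout 2, glycolysis 0.338 without Itgb1 knockout 1, interstitial matrix 0.436 without labelled double knockout 5 and macrophages 0.329 without labelled double knockout 4. The cell cycle had −0.215 without Itgb1 knockout 2 and −0.199 without labelled double knockout 4.

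Against the Itgb3 knockouts, 338 genes rose and 70 fell in the tumours labelled double knockout, and 3009 had an unadjusted p under 0.05. The chitinase gene Chit1 rose by 2.72 (SE 0.676, adjusted p = 0.0375), Samd5 by 2.70 (SE 0.363, adjusted p = 0.00193), the carboxypeptidase gene Cpm by 2.69 (SE 0.61, adjusted p = 0.028), the interleukin 18 receptor gene Il18r1 by 2.01 (SE 0.505, adjusted p = 0.0399) and the desmosomal cadherin gene Dsg3 by 1.79 (SE 0.417, adjusted p = 0.0307). The genes that fell most were Gabra4 (−5.09, SE 0.593, adjusted p = 0.00055, −3.82 with values raised to the filter), the secreted salivary protein gene Dcpp2 (−3.66, SE 0.97, adjusted p = 0.048), the Rag GTPase gene Rragd (−1.76, SE 0.427, adjusted p = 0.0341), Itgb1 (−1.72, adjusted p = 0.00055) and Rtp4 (−1.71, SE 0.436, adjusted p = 0.0424). Of the genes that passed against control, 30 were also higher here (0.998 expected if independent) and 7 also lower (0.0639 expected), and both comparisons use the same 6 tumours.

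The arrays of the 2 groups differed in level, with medians of 4.32 to 4.34 in the labelled double knockouts and 4.41 to 4.48 in the Itgb3 knockouts: 1167 genes were higher and 53 lower with arrays centred, and 0 passed with the array median as a covariate. The count of 408 was 56, 119, 126 and 66 without Itgb3 knockout replicates 1, 2, 3 and 4, and 132 and 227 without labelled double knockout replicates 1 and 2.

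Matrix and adhesion lists were higher here too, and each list is given with its mean, its adjusted p and its adjusted p with an estimated correlation. Interstitial matrix (0.796, 2.84e-07, 0.362) had 4 members higher over all genes and 13 over the list alone, among them Col15a1 (0.99, adjusted p = 0.0223) and Col6a3 (0.86, adjusted p = 0.0297). Focal adhesion (0.353, 1.4e-05, 0.0855) had 1, Tgfb1i1 (0.76, adjusted p = 0.0466), and 15 over the list alone. Basement membrane (0.435, 2.23e-05, 0.147) had 4, with Hspg2 (0.88, adjusted p = 0.00998) and Lamb1 (0.86, adjusted p = 0.0163), and 9 over the list alone. Integrin subunits (0.349, 0.00136, 0.147) had 4 higher and 1 lower, with Itgb4 (1.05, adjusted p = 0.0163) and Itga2 (0.93, adjusted p = 0.0163) higher, and 9 higher and 1 lower over the list alone. Proteases and inhibitors (0.453, 0.000738, 0.362) had 2 and 6, with Adamts1 (0.84, adjusted p = 0.0348).

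Among cell types, macrophage markers (0.498, 6.19e-05, 0.362) had 3 higher over all genes and 4 over the list alone, with Adgre1 (0.98, adjusted p = 0.0163) and Cd14 (1.19, adjusted p = 0.0182). Pericytes (0.501, 0.0011, 0.231) had 0 and 5, fibroblasts (0.525, 0.0136, 0.654) 1 and 2, with Col14a1 (1.47, adjusted p = 0.0381), endothelium (0.296, 0.00323, 0.565) 1 and 6, with Ptprb (0.84, adjusted p = 0.0313), and basal markers (0.405, 0.00136, 0.289) 1 and 4, with Jag1 (1.20, adjusted p = 0.0111). Mesenchymal genes (0.422, 0.00323, 0.362) had 2 and 4, with Wnt5a (0.91, adjusted p = 0.0182) and Mmp14 (1.18, adjusted p = 0.0296). TGF-beta response (0.331, 0.000698, 0.147) had 2 higher and 1 lower, then 5 and 1, with Smurf2 (0.50, adjusted p = 0.0319) and Ltbp4 (0.73, adjusted p = 0.0337). The insulin and IGF pathway (0.252, 0.00334, 0.147) had 1 and 2, with Igfbp4 (1.14, adjusted p = 0.014), and YAP and TAZ targets (0.372, 0.00174, 0.178) 0 and 2, with Ccn2 at 0.84. Interferon response genes were lower (−0.937, 3.52e-07, 0.362), with 0 members past by either adjustment and Usp18 at −2.33 (adjusted p = 0.0947). Milk protein and secretory genes were lower (−0.451, 0.0179, 0.362), with 0 past over all genes, 1 higher and 3 lower over the list alone, and Thrsp at −1.68 and Csn1s2a at −2.01. Fibroblasts (lowest mean 0.276) did not pass without Itgb3 knockout 2 or labelled double knockout 2 or 3, and had a mean of 0.826 without Itgb3 knockout 3. Interstitial matrix had a mean of 0.505 without Itgb3 knockout 2 and passed. Milk protein genes did not pass without Itgb3 knockout 2 or labelled double knockout 4 (−0.378). These are 16 lists of 33. Over all 33 lists, these 16 or not, 0 passed with an estimated correlation and 14 passed in fry.

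Between the single knockouts 0 genes passed in limma (Itgb3 against Itgb1 knockouts, 647 with an unadjusted p under 0.05, smallest adjusted p = 0.131). Itgb1 was 1.34 higher (SE 0.223, adjusted p = 0.131) and Itgb3 differed by −1.23 (adjusted p = 0.524), as did Cyb561a3, a cytochrome gene, by −0.65 (adjusted p = 0.524). The count was 1 without labelled double knockout replicate 5, which enters only through the shared spread. Of the lists 6 passed, 0 with an estimated correlation and 0 in fry. Interstitial matrix (mean −0.535, adjusted p = 2.4e-06, adjusted p = 0.746 with an estimated correlation, Col14a1 −1.11, or −0.70 without Itgb3 knockout 2), fibroblasts (−0.603, 0.000316, 0.746, Lum −1.26), macrophages (−0.298, 0.00241, 0.746, Adgre1 −0.53), basement membrane (−0.196, 0.0133, 0.746, Nid1 −0.61) and focal adhesion (−0.148, 0.0288, 0.746, Rsu1 −0.26) were lower in the Itgb3 knockouts. Glycolysis and hypoxia genes were higher (0.173, 0.00857, 0.77, Pfkl 0.35), with 24 of 26 members above 0. Of the members 0 passed by either adjustment. With the 2 Itgb3 knockouts under the intensity filter raised to it, Lum differed by −0.90.

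Without Itgb3 knockout 2 the interstitial matrix mean was −0.244 and the fibroblast mean −0.355, and neither list passed. Without Itgb3 knockout 3 the fibroblast mean was −0.905. Macrophages (−0.227 at the smallest) were lost without Itgb1 knockout 1 or Itgb3 knockout 2, focal adhesion (−0.119) without Itgb1 or Itgb3 knockout 1 or 2, and basement membrane (−0.156) without Itgb1 knockout 1 or 2 or Itgb3 knockout 2 or 3. Glycolysis was lost without Itgb1 knockout 3 (0.0618) and without Itgb3 knockout 1, where its mean turned to −0.00805 although the test pointed higher. Its mean was 0.315 without Itgb1 knockout 1 and 0.318 without Itgb3 knockout 2. With the array median as a covariate it turned to −0.00163 and was lost.

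The interaction compares the labelled double knockouts with the sum of the single knockout differences, and 0 genes passed in limma (1777 with an unadjusted p under 0.05). The homeobox gene Lhx2 (−0.99, SE 0.174), the neuroligin gene Nlgn2 (0.95, SE 0.171) and the TNF receptor gene Tnfrsf1b (1.25, SE 0.232) came nearest, each with an adjusted p of 0.0963. Itgb3 had an interaction of 1.01 (SE 0.352, adjusted p = 0.271), since it was low in the Itgb3 knockouts and not in the tumours labelled double knockout. The count was 5 without control replicate 2, 2 without Itgb1 knockout replicate 1, and 1 without Itgb3 knockout replicate 3 or labelled double knockout replicate 5.

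Of the lists 15 had an interaction, 12 above and 3 below 0. Over all 33 lists, 0 passed with an estimated correlation and 4 passed in fry. Focal adhesion had a mean of 0.399 (adjusted p = 2.05e-05, adjusted p = 0.069 with an estimated correlation, Git1 0.82), basement membrane 0.428 (0.000544, 0.247, Lamb1 1.17, 4 past over the list alone), interstitial matrix 0.582 (0.00186, 0.713), YAP and TAZ targets 0.405 (0.00186, 0.247), pericytes 0.528 (0.00275, 0.281), basal markers 0.45 (0.00275, 0.281, Jag1 1.26) and integrin subunits 0.339 (0.00607, 0.274, Itgb4 0.96). TGF-beta response had 0.272 (0.00983, 0.281), macrophages 0.345 (0.0135, 0.713), proteases 0.336 (0.0225, 0.713), the insulin and IGF pathway 0.198 (0.0225, 0.247) and glycolysis 0.257 (0.0405, 0.713). Milk protein and secretory genes had −0.772 (0.00275, 0.281, Thrsp −2.67, 3 past over the list alone), interferon response −0.593 (0.0225, 0.713, Mx2 −1.21) and the cell cycle −0.19 (0.0225, 0.759, Pcna −0.58). With the adjustment over the list alone, 1 gene each of focal adhesion, basal markers, the insulin and IGF pathway and glycolysis lay above 0 and 1 TGF-beta gene below.

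Interstitial matrix (lowest mean 0.292) did not pass without Itgb3 knockout 2, nor did TGF-beta response (0.211) without Itgb1 knockout 3. Macrophages (0.250) were lost without control 4, Itgb1 knockout 3 or labelled double knockout 2, the insulin and IGF pathway (0.168) without Itgb1 knockout 3 or 4, Itgb3 knockout 2 or labelled double knockout 6, and proteases (0.217) without control 4 or 5, Itgb1 knockout 3, Itgb3 knockout 2 or labelled double knockout 2. Interferon response genes ran from −0.942 (without Itgb3 knockout 4) to −0.303 (Itgb1 knockout 2), glycolysis from 0.113 (Itgb3 knockout 2) to 0.438 (Itgb3 knockout 1) and the cell cycle from −0.321 (control 1) to −0.0672 (labelled double knockout 5). Glycolysis was also 0.423 without control 3 and 0.399 without Itgb1 knockout 1, and the cell cycle −0.317 without Itgb3 knockout 2. Interferon genes were lost without control 1 or 4, Itgb1 knockout 2 or 4, Itgb3 knockout 1 or 2, or labelled double knockout 2 or 4. Glycolysis was lost without control 1, 4 or 5, Itgb1 knockout 2, 3 or 4, Itgb3 knockout 2 or 3, or labelled double knockout 2, 4 or 6. The cell cycle was lost without control 2, 3 or 4, Itgb1 knockout 3 or 4, any Itgb3 knockout but 2, or labelled double knockout 1 or 5.

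Genes of distal chromosome 11 shifted together in the tumours labelled double knockout. Against control the search along the chromosomes gave 12 stretches. The highest window was on chromosome 1 (mean 0.402), and 2 separate stretches lay on chromosome 11, Arf2 to Birc5 (147 genes, highest window 0.333) and Faap100 to Metrnl (45 genes). After they were seen they were joined with the genes between them. The joined stretch runs from Arf2, 5 genes before Itgb3, to the end of the chromosome and has 230 genes, 1.62% of those tested. Of the 55 genes that passed against control it held 12, all higher: Cyb561 (0.80), Ace (1.26), Dcaf7 (0.84), Tex2 (0.71), Ddx5 (0.63), Prkca (1.23), Cep112 (0.60), Slc16a6 (1.80), Itgb4 (0.91), Unc13d (0.71), Endov (0.49) and Rptor (0.58). The mean over its genes was 0.264 (SE 0.0469) against control, 0.288 (SE 0.05) against the Itgb3 knockouts and 0.237 (SE 0.05) against the Itgb1 knockouts, and 82.2% of its genes lay above 0 against 56% of all placed genes. In the single knockouts the mean was 0.0274 (SE 0.0519) for Itgb1 and −0.0242 (SE 0.0519) for Itgb3. Because the stretch was chosen by this search for its high mean, its p is not given, and its mean, its share above 0 and its number of called genes against control owe part of their size to the choice.

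**Figure D5:**
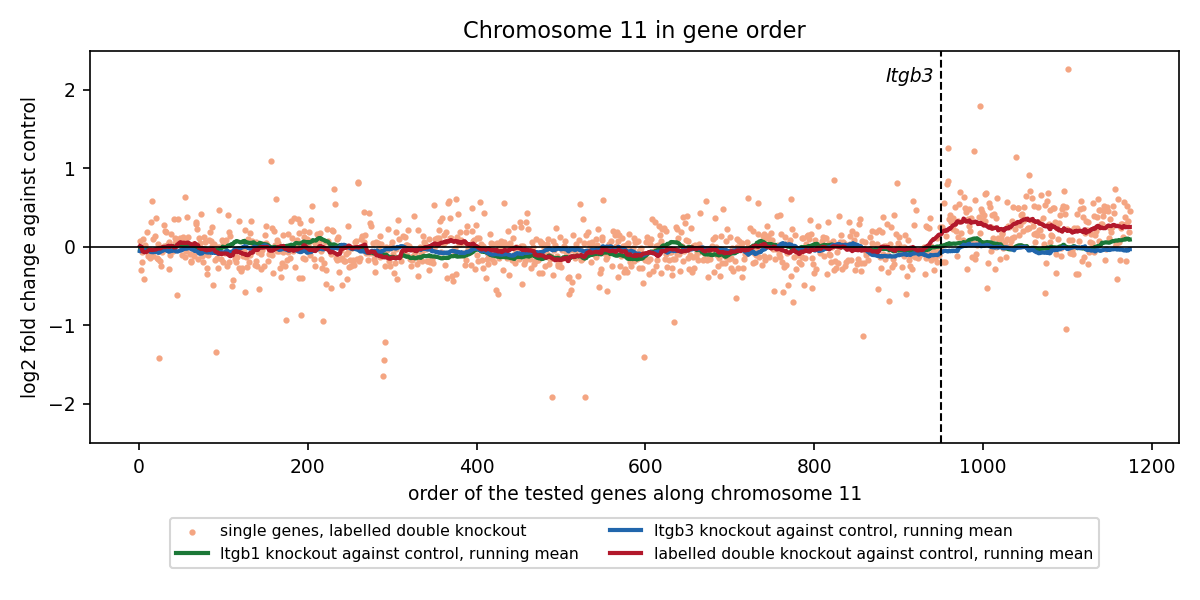
Log2 difference from control of the 1174 tested genes of chromosome 11 in gene order, with a running mean over neighbouring genes for each knockout group. The mean rises from Arf2 onward only in the tumours labelled double knockout (0.264 over the stretch).

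The differences of the knockout groups from the shared controls were correlated across genes at r = 0.489 for the single knockouts, 0.418 for the Itgb1 and labelled double knockouts and 0.182 for the Itgb3 and labelled double knockouts. Unchanged groups with shared controls gave 0.446, 0.471 and 0.443 in simulation, and splitting the controls gave −0.0367, 0.0378 and −0.139. The covariances were 0.0231, 0.0285 and 0.012 beside simulated ones of 0.0239, 0.022 and 0.0202. In the same order, single simulations gave correlations from −0.165 to 0.857, from −0.376 to 0.921 and from −0.339 to 0.91. The shared controls alone can thus give correlations of this size, and 0.182 lay below its simulated mean of 0.443. Ranges this wide leave room for many other values too.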

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

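The tests of alleles linked to Itgb3, of extra copies, of the neighbours of Itgb3, of Itgb3 alleles not deleted and of the array level, that of fibroblasts and fat for the excess of higher genes, and the array median covariate were chosen only after the result was seen.

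Some tumours stood apart from the others of their group. In Itgb1 knockout replicate 3 Cyp4b1 was 6.27 (5.67 to 5.72 in the other 3), in replicate 2 Pygl was 6.82 (5.98 in the other 3), and in replicate 1 Zfp329 was 7.12 (6.32 to 6.45). Zfp329 was also high in Itgb3 knockout replicate 1 (6.58, against 6.28 to 6.31 in the others). Gabra4 was 4.94 in labelled double knockout replicate 2 and 2.56 to 3.20 in the other 5 tumours. The mean of the milk protein and secretory genes was 7.53 in Itgb3 knockout replicate 4 and 7.99 to 8.03 in the other 3. Chance gives such a gap in about 1 of 20 groups, so the 5 gaps among 200 sets of gene values and the 1 among 76 sets of list means are no more than chance gives.

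By the list test with a preset correlation, 15 lists in the tumours labelled double knockout lay off the sum of the single knockout differences, and 0 passed with an estimated correlation (smallest adjusted p = 0.069). Lists with a mean above that sum were integrin subunits (0.339), focal adhesion (0.399), basement membrane (0.428), interstitial matrix (0.582), pericytes and smooth muscle (0.528), macrophages (0.345), basal and myoepithelial markers (0.45), the insulin and IGF pathway (0.198), glycolysis and hypoxia (0.257), YAP and TAZ targets (0.405), TGF-beta response (0.272) and matrix proteases and inhibitors (0.336). Milk protein and secretory genes (−0.772), the cell cycle (−0.19) and interferon response genes (−0.593) lay below it. Itgb3 had an interaction of 1.01 that did not pass (adjusted p = 0.271). For the 15 lists chance was not excluded, since 9 of 100 splits of the tumours gave as many lists and the highest other split gave 19. For genes 0 passed in limma, a count that all 100 splits must reach (highest other 1), so nothing about chance follows.

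Among 7782 probe sets with no symbol or several symbols, which the gene counts leave out, 2 passed in the Itgb3 knockouts against control (1 higher, 1 lower), 29 in the tumours labelled double knockout against the Itgb3 knockouts (16 higher, 13 lower), 1 between the single knockouts and 1 in the interaction.

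Other splits of the same tumours tested whether chance gives as many calls. For the labelled double knockouts against control 1 of 100 splits, the real one, reached the 55 genes, with 18 in the highest other. Against the Itgb3 knockouts 1 of 100 reached the 408 genes, with 63 in the highest other. Chance is thus unlikely for both counts, although 100 draws cannot exclude it. Against the Itgb1 knockouts 4 of 100 splits reached the 3 genes (highest other 12). With no adjustment over the comparisons, chance was not excluded there. Nor was it excluded for the Itgb1 knockouts against control (1 gene, 14 of 100, highest other 8). Every split reaches a count of 0, so nothing about chance follows for the Itgb3 knockouts against control (0 genes, 100 of 100, highest other 1) or between the single knockouts (0 genes, 35 of 35, highest other 2). The highest splits of 8 genes beside 1 and of 12 beside 3 exceed the real counts, although only 13 and 9 of the other splits called any gene. Whether a structure of the samples gave these splits was not tested. For lists chance was excluded in no comparison: 92 of 100 splits reached the 2 lists of the Itgb1 knockouts (highest other 18) and 82 of 100 the 4 of the Itgb3 knockouts (highest other 16). Likewise 13 of 100 reached the 15 of the labelled double knockouts against control (highest other 19), 7 of 100 the 15 against the Itgb1 knockouts (highest other 20), 10 of 100 the 16 against the Itgb3 knockouts (highest other 20), and 19 of 35 the 6 between single knockouts (highest other 17).

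Distal chromosome 11, which holds Itgb3, lay above the control mean in all 6 tumours labelled double knockout (0.337, 0.405, 0.188, 0.299, 0.15 and 0.205 for replicates 1 to 6, against −0.0879 to 0.152 in the other 13). Alleles linked to a floxed Itgb3 gene that raise the stretch as a whole and are carried by both groups would also shift the Itgb3 knockouts. There the mean was −0.0242 (SE 0.0519), which argues against such a shared shift of the whole stretch. A mean over the stretch cannot show shared alleles that move single genes in either direction, so those stay open. Alleles carried only by the labelled double knockouts were not tested. Another share of fibroblasts and fat is argued against as the whole source, because the mean was 0.246 (SE 0.0443) with the fibroblast and adipocyte covariates and 0.264 without them. Pericytes, endothelium, macrophages and other stromal cells were not used as covariates, so their share was not tested. Extra copies of the stretch in tumour cells were not tested, because the 82.2% of its genes above 0 largely follow from the choice of the stretch and no DNA was analysed here, so copies and regulation of the stretch cannot be told apart. The biological explanation the design gives, the genotype on the label, stays open and untested.

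Itgb3 was not lower in the tumours labelled double knockout. More endothelial cells and macrophages, which carry Itgb3, were tested with the means of both lists as covariates. The difference from control was 0.162 (SE 0.26) with them and 0.0131 without, both far above the −1.12 of the Itgb3 knockouts. Both lists were higher in these tumours, yet the covariates raised the difference instead of lowering it. The fit thus could not have removed a share from such cells, and the test cannot decide this. A shift shared with its neighbours is argued against as the whole source, because the 20 genes on each side averaged 0.2 (SE 0.0411) above the Itgb3 knockouts and Itgb3 itself 1.13. Itgb3 alleles that were not deleted could leave this level, with 6 of 6 tumours above the highest Itgb3 knockout on a probe set that was lower in that group. No genotype was analysed here, and more transcript from cells that keep the gene was not tested, so these cannot be told apart.

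Far more genes were higher than lower in the tumours labelled double knockout against the Itgb3 knockouts (338 and 70). Another mix of fibroblasts and fat is argued against as the whole source, while other stromal cells were not used as covariates. Of the genes with an unadjusted p under 0.05, 67.1% were higher with the fibroblast and adipocyte covariates (65.4 to 69.9% without each tumour) and 66.2% without them. The calls dropped to 60 as the median difference of the 338 went from 0.674 (SE 0.154) to 0.639 (SE 0.164). With the array median as a covariate the share of higher genes was 53.1% (50.6 to 56.4%), and with quantile normalization 59.6%. With the array median the calls went from 408 to 0, at a median difference of 0.617 (SE 0.213), because the standard errors grew. The array medians of the 2 groups do not overlap, so the array level left by the authors' normalization cannot be told apart from the genotype, and the loss of Itgb1, which the groups also differ in, stays open and untested.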

How the results depend on the processing

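The array median covariate and the omission of distal chromosome 11 were chosen only after the result was seen. No paired analysis was possible because the labels give no replicate number shared between groups. The lists used as covariates were not tested under their own covariate, and the groups compared alone could not be fitted for the interaction. The array of low correlation was control replicate 5. Leaving it out therefore repeats the setting without that tumour, and the counts of settings for named genes below hold both.

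The Itgb1 level in the Itgb1 knockouts (−1.55 to −1.36 without each tumour) and the Itgb3 level in the Itgb3 knockouts (−1.25 to −0.89) kept their direction and an unadjusted p under 0.05 in all settings. Of the named genes that passed, 537 settings gave the same side and 229 lost it, and without each tumour 758 kept it and 306 lost it. Of the named genes that did not pass, 2054 settings gave the same, 47 passed and 13 reversed, and without each tumour these were 2890, 42 and 32. Of the lists that passed, 378 settings kept it and 131 lost it, and without each tumour 1230 kept it, 156 lost it and 1 reversed by its test. The 131 include all 73 list results with an estimated correlation. The mean of glycolysis between single knockouts turned to −0.00163 with the array median covariate and to −0.00805 without Itgb3 knockout 1, while its test kept its direction.

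The count of the labelled double knockouts against control (55) was 31 with quantile normalization, 100 with arrays centred, 27 with no filter, 2 with only the groups compared, 26 with intensity trend and robust moderation, 31 with array weights, 28 with the fibroblast and adipocyte covariates, 10 with the B and plasma cell covariate, 17 with a plain t statistic, 105 without the array of low correlation, 19 with the array median covariate, 20 with a size of at least 1 and 17 without distal chromosome 11. It ran from 14 to 125 without each tumour. Of the 55 genes 53 were shared with the 100, and 30 with the 31 of quantile normalization. Without distal chromosome 11 fewer genes were tested and 12 of the called ones were gone. For the rest the cause was not tested.

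The count of the Itgb1 knockouts against control (1) was 0 with array weights, the fibroblast and adipocyte covariates, a plain t statistic and without the array of low correlation (0 to 1 without each tumour). The count of the labelled double knockouts against the Itgb1 knockouts (3) was 7 with only the groups compared, 33 with array weights, 6 without the array of low correlation, and 0 with either kind of list covariate, a plain t statistic or the array median covariate (0 to 24 without each tumour). Against the Itgb3 knockouts (408) it was 232 with quantile normalization, 1220 with arrays centred, 1568 with array weights, 60 with the fibroblast and adipocyte covariates, 0 with the array median covariate and 65 with a size of at least 1 (56 to 459 without each tumour). Between single knockouts (0) it was 1 with the fibroblast and adipocyte covariates and with a plain t statistic (0 to 1 without each tumour). For the interaction (0) it was 3 with array weights and 1 with a plain t statistic (0 to 5 without each tumour). The cause was not tested. With arrays centred the median difference of all genes was 0.142 instead of 0.0317 for the labelled double knockouts against the Itgb3 knockouts, −0.104 instead of −0.0327 between single knockouts and 0.113 instead of 0.00692 for the interaction.

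The number of lists was 0 in all 7 comparisons with an estimated correlation. In the Itgb1 knockouts (2) it was 8 with no filter and 0 in fry in one or either direction (1 to 9 without each tumour). In the Itgb3 knockouts (4) it was 10 with the B and plasma cell covariate and 0 in fry in one or either direction (2 to 9). In the labelled double knockouts it was 8 with the B and plasma cell covariate and 9 in fry against control (15, with 8 to 17), and 7 with that covariate and 3 in fry against the Itgb1 knockouts (15, with 4 to 17). Between single knockouts (6) it was 11 with no filter, 2 with the fibroblast and adipocyte covariates, 0 in fry and 1 in fry in either direction (1 to 9). For the interaction (15) it was 4 in fry and 7 in fry in either direction (9 to 17). The cause was not tested. The correlations between knockouts were −0.0367, 0.0378 and −0.139 with split controls, which removes the shared part.

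Differences close to 0 reversed. Itgb3 in the labelled double knockouts against control was −0.0412 with quantile normalization and −0.025 with array weights (−0.0877 to 0.10 without each tumour), and in the Itgb1 knockouts −0.0172 with array weights (−0.13 to 0.23). Erbb2 against the Itgb3 knockouts was −0.0228 with quantile normalization (−0.0136 to 0.14). Insr between single knockouts was 0.0419 with quantile normalization, 0.0028 with array weights and 0.0313 with the B and plasma cell covariate (−0.14 to 0.0488), and in the Itgb3 knockouts 0.0070 with that covariate (−0.17 to 0.0125). Igf1r in the Itgb3 knockouts was −0.0111 with arrays centred and −0.0717 with the B and plasma cell covariate (−0.12 to 0.27), in the labelled double knockouts 0.0664 without the array of low correlation (−0.29 to 0.11), and in the interaction −0.0359 without that array and −0.21 with the array median covariate (−0.10 to 0.31). Leaving out single tumours also reversed Insr in the Itgb1 knockouts (−0.11 to 0.0764), the interstitial matrix list in the Itgb3 knockouts (−0.53 to −0.0302, by its test), Erbb2 in the labelled double knockouts (−0.17 to 0.0333), between single knockouts (−0.0648 to 0.21) and against the Itgb1 knockouts (−0.0140 to 0.26), where Itgb3 (−0.22 to 0.15) and Igf1r (−0.0337 to 0.36) reversed too, and Igf1r against the Itgb3 knockouts (−0.35 to 0.0540). The cause was not tested. No background level was used here, so which low values are background is not known.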

Other observations

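The tests of Itgb1 against the size of the chromosome 11 shift and of 7 lists of stromal and immune cells and matrix against it were chosen only after the result was seen, and the search along the chromosomes was not tied to a hypothesis.

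Other stretches of neighbouring genes also passed the cutoff of that search in the tumours labelled double knockout against control (0.241 for the mean of 40 genes, with 0.301 the highest of the shuffled orders). The search gave 12 stretches there, 17 in the Itgb1 knockouts and 6 in the Itgb3 knockouts against control. The cutoffs for the single knockouts were lower (0.174 and 0.167), so the numbers of stretches are not comparable. Their highest windows, 0.25 and 0.349, lay above 0.241, so windows past that level are not particular to the labelled double knockouts. The 0.349 window lay in a stretch of chromosome 5 with a mean of 0.184 and a median of 0.087, so a few genes made much of it. The stretch of chromosome 14 with the 0.25 window had a median of 0.234. Arf2 to Birc5 had one of 0.258 in the labelled double knockouts. In the labelled double knockouts the highest window had a mean of 0.402 on chromosome 1, and the lowest −0.288 on chromosome 14. Stretches of chromosome 1 were higher in all 3 knockout groups, which share their controls. Chromosome 1 also held higher stretches in the labelled double knockouts against each single knockout group, differences that leave the controls out. Its highest windows were 0.44 against the Itgb1 and 0.317 against the Itgb3 knockouts, beside 0.371 and 0.367 on chromosome 11. Chromosome 14 held lower windows in both (−0.278 and −0.305). Distal chromosome 11 was thus not the only part that differed in these comparisons. Single tumours departed by a whole chromosome: the median over chromosome X was −0.413 in control replicate 2, over chromosome 18 −0.363 in labelled double knockout replicate 6 and over chromosome 15 0.286 in labelled double knockout replicate 2.

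The shift of distal chromosome 11 was larger in the labelled double knockouts with less Itgb1. Across the 6 tumours Itgb1 and the mean of the stretch had a Pearson correlation of −0.837 (exact two-sided permutation p = 0.0208) and a Spearman correlation of −1 (exact permutation p = 0.00278, the smallest possible with 720 arrangements). A larger share of cells that lost Itgb1 was the hypothesis tested. With fewer stromal cells in those tumours the fibroblast list would fall as the stretch rises, but its correlation with the stretch was 0.615 (exact permutation p = 0.188), that of interstitial matrix 0.773 (0.0514), that of pericytes 0.382 (0.457), that of macrophages 0.355 (0.49), that of endothelium 0.279 (0.586), that of adipocytes 0.0165 (0.974) and that of T and NK cells −0.252 (0.626). Of these 0 had a p under 0.05. With Itgb1 itself interstitial matrix had a correlation of −0.907 (0.0333), fibroblasts −0.68 (0.124) and T and NK cells 0.674 (0.131). More matrix and fibroblast signal where Itgb1 was lower runs against the hypothesis, T and NK cells do not, and 6 tumours do not settle it.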
